A study of Mus musculus with 4 samples.

How the data were processed

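RNA from mouse skin was measured by sequencing in 4 libraries, 2 labelled wild type (WT) and 2 labelled as lesional skin of Itch knockout mice. Groups and replicate numbers were taken from the sample labels. The values were read counts per Ensembl gene, deposited by the authors as 1 file per library without normalization. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2, SAMtools 0.1.19 and HTSeq 0.6.1 were used with the mm10 (GRCm38) build. The TopHat2 version, the annotation release, the strand setting of the counting and any read filters are not given in the sources used here. Counting without strand would add reads of an overlapping gene on the opposite strand, so such genes are reported as uncertain. Counts of near-identical gene copies are uncertain for the same reason of shared reads.

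Each file held 39179 genes and 5 special counter lines, which stayed out of library sizes and tests. Reads without a feature made up 7.45% and 6.80% of counted reads in WT replicates 1 and 2 and 6.79% and 5.68% in knockout replicates 1 and 2. Ambiguous reads made up 4.61%, 4.48%, 4.50% and 4.70% in the same order, and the counters for low quality, unaligned and multiply aligned reads were 0. Gene reads numbered 15407932, 15144957, 16008351 and 15881860. A count of 0 allows a level of up to 0.195, 0.198, 0.187 and 0.189 CPM (counts scaled to library size) at a floor of 3 counts per library. Folds against a group at 0 used a floor of 3 counts over the group. Floors and intervals cover counting error only. Gene symbols and GRCm38 coordinates came from GENCODE vM21, which held 37607 of the 39179 identifiers, and 14605 genes had 0 counts in all libraries.

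Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 16651 genes, and libraries were scaled by TMM. CPM values are relative to TMM-scaled library sizes. Groups were compared by the quasi-likelihood F test (legacy=TRUE, robust=TRUE, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 0.341 and the median prior degrees of freedom were 2.40. Fold changes are log2 of knockout over WT with standard errors (SE). Replicate agreement was the Pearson correlation of log2(CPM + 1) across genes. Counts of the libraries of each group differed by more than sampling noise, with a chi-square per degree of freedom of 117 in WT and 25.2 in the knockouts.

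A set of 36 gene lists for pathways, skin compartments, cell types and technical signs was written down before the data were examined, and 12 of their symbols had no match. Lists were tested with camera on the edgeR fit with a preset correlation of 0.01, adjusted over the 36 lists. The list of proteins described as Itch partners and the p38 list came from general knowledge of Itch. Of the lists, 27 passed, 22 higher and 5 lower in the knockouts, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.305. That version uses only the few residual degrees of freedom of 4 libraries, so a pass over 36 lists was hardly possible. The chemokine, immediate early and type 2 lists had estimated correlations of -0.036, -0.012 and 0.006, below the preset, and lost their calls too. A call lost in this way is therefore no sign of correlation among the members. With fry, a directional test of each list on its own, 5 passed: the type 2, chemokine, eosinophil, immediate early and sex-linked lists. In all, 18 genes stood on several lists. Bulk skin gives marker levels and not cell shares.

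Named genes followed a rule fixed before the data were examined. It took Itch, then up to 10 genes with the largest rise and up to 10 with the largest fall among those past the threshold with a mean of 5 CPM or more and both knockouts on the same side of both WT libraries. Unnamed predicted genes and antigen receptor segments were left out, with at most 3 genes of a family. It then took Tnf, Il1b, Il6, Il11, Il19, Il17a, Junb, Tab1, Mapk14 and Asip, and from each list the genes with the smallest p, up to 3 for main lists and 2 for the others. Since 1 gene passed, the rule for the largest changes named Eif2s3y alone. A gene that the rule named is not reported here. Ddx3y, Uty, Kdm5d, 2310005A03Rik, the Skint genes, Tcrg-V5, Trdv4, Fcgr2b, Clec10a, Pf4, Folr2, S100a8, Arntl, Npas2, Nr1d1, Nr1d2, Per3 and Dbp were named after their values were seen. Genes within 5 Mb of Itch, Itch itself left out, were compared with all other tested genes by Fisher's exact test.

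The procedure was tested on simulated counts with the real means and library sizes and 200 genes changed 2-, 4- or 16-fold. With a spread drawn gene by gene, on 16369 genes, edgeR recovered 0%, 13.4% and 47.0% of changed genes at those folds with 0 false among 40 calls. DESeq2 recovered 49.3%, 79.1% and 97.0% with 197 false among 347 calls, and limma-voom 0%, 13.4% and 50.0% with 0 false among 42. The gene-by-gene spread was each gene's own estimate without moderation, so error in the estimates acted as true differences between genes. With the fitted trend as the spread, on 16383 genes, edgeR recovered 4.48%, 55.2% and 100% with 1 false among 107 calls, and DESeq2 7.46%, 62.7% and 100% with 16 false among 129. With that trend divided by 10, on 16459 genes, edgeR recovered 91.0%, 98.5% and 100% with 5 false among 198 calls. The gene-by-gene simulation was added after the trend simulation had shown a higher recovery than the real spread warranted.

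Alternatives fixed before the data were examined were DESeq2 size factors, TMM without the 200 most abundant genes, library size alone, no filter, a filter of 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), the newer quasi-likelihood of edgeR, a test against a fold of 1.5, a replicate block, each library left out in turn, estimated correlation, fry, lists without shared genes, windows of 1 and 10 Mb, and other pseudocounts of 0.25 and 5. With a library left out, the spread came from the intact pair of the other group alone, and the lone library was assumed to vary like that pair, for genes and lists alike. Chosen after seeing the data were the fit without X and Y genes, the fit without robust moderation, an adjusted p under 0.10, the DESeq2 calls near Itch, and the Nedd4 family list without Itch. DESeq2 gave no adjusted p for 323 genes, which were not called.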

Results

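The data were gene-level read counts from 4 RNA sequencing libraries of mouse skin on the C57BL/6 background, 2 from wild-type (WT) mice and 2 from lesional skin of mice without Itch. The labels give inflammation as the phenotype of all 4 samples, WT included. Itch is a ubiquitin ligase of the Nedd4 family whose loss in mice is known for inflammation and scratching. The comparison asked how the skin transcriptome of these mice differed from WT skin. Reads assigned to genes numbered 15407932 and 15144957 in WT replicates 1 and 2, and 16008351 and 15881860 in knockout replicates 1 and 2. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries.

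Itch mRNA was far lower in both knockout libraries. The gene (ENSMUSG00000027598, GRCm38 chromosome 2, 155133509 to 155226855, plus strand) had 1450 and 1634 counts in WT and 185 and 184 in the knockouts. As counts scaled to library size (CPM), these were 96.7 and 103 against 11.7 and 11.7, a log2 fold change of -3.09 (SE 0.16). The edgeR quasi-likelihood test gave adjusted p = 0.0509, just above the threshold, and DESeq2 gave adjusted p = 1.77e-37. Without WT replicate 1 or without WT replicate 2, edgeR gave adjusted p = 0.00188 and 0.000233, but the spread then came from the 2 knockout libraries alone and the lone WT library was assumed to vary like them. Without knockout replicate 1 or 2 it did not pass, with adjusted p = 0.279 and 0.196 and log2 fold changes of -3.10 and -3.09. In each of the 4 libraries the Itch level lay on the side of its labelled genotype.

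The genotypes also differed in sex-linked transcripts. Xist, made from the inactive X chromosome, stood at 1055 and 631 CPM in WT and at 0.947 and 0.892 CPM in the knockouts. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y summed to 0.267 and 0.316 CPM in WT and to 176 and 154 CPM in the knockouts. By these transcripts, both WT libraries came from females and both knockout libraries from males, so each comparison of genotypes given here was also a comparison of sexes. Kdm5d had 0 counts in both WT libraries, and its knockout level was at least 179-fold higher than the floor of 3 counts over the group. The sex-linked list (5 genes tested) passed the list test with adjusted p = 1.03e-05, and adjusted p = 0.327 with an estimated correlation. Over all genes 1 member rose, Eif2s3y, and all 5 passed when adjusted over the list alone, 4 higher and 1 lower. DESeq2 called the same numbers in each direction. The list's median of 9.02 became 7.89 with Kdm5d set at its bound.

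The WT libraries differed from each other more than the knockout libraries did, and WT replicate 2 was closer to both knockout libraries than to WT replicate 1. Across tested genes, the Pearson correlation of log2(CPM + 1) was 0.923 between the WT libraries and 0.983 between the knockout libraries, with genes not being independent replicates. Against knockout replicates 1 and 2 it was 0.931 and 0.945 for WT replicate 2, and 0.849 and 0.850 for WT replicate 1. Muscle and hair genes were among those that differed between the WT libraries. Actn3, an actin-binding protein of fast muscle fibres, stood at 1179 CPM in WT replicate 1 and 140 in WT replicate 2, against 32.5 and 25.2 in the knockouts. Krtap14, a keratin-associated protein of the hair shaft, stood at 0.267 CPM in WT replicate 1 and 48.0 in WT replicate 2, against 210 and 118 in the knockouts.

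Across the transcriptome, 1 of 16651 tested genes passed adjusted p under 0.05 in edgeR, the Y-linked translation factor gene Eif2s3y (ENSMUSG00000069049). It rose from 0.133 and 0.126 CPM in WT to 69.5 and 73.7 CPM in the knockouts (log2 fold change 9.02, SE 0.26, adjusted p = 0.0269). Many genes lay close to the threshold: 789 had adjusted p under 0.10, a wider threshold chosen after seeing the data, and 3802 had an unadjusted p under 0.05, 1995 higher and 1807 lower in the knockouts. Both knockout libraries lay above both WT libraries for 31.2% of tested genes and below them for 30.0%, where random ordering gives 16.7% each way. DESeq2 called 1304 genes higher and 1025 lower and limma-voom called 0, with 3566 genes at an unadjusted p under 0.05. In simulated counts with a spread drawn gene by gene, 197 of 347 DESeq2 calls and 0 of 40 edgeR calls were false. With the fitted trend as the spread, 16 of 129 DESeq2 calls and 1 of 107 edgeR calls were false. These shares depend on how many genes were set as changed, so they do not give the false share of the real calls. With X and Y genes left out, a fit also chosen after seeing the data, edgeR called 0 genes, with 3649 at an unadjusted p under 0.05. Leaving out a WT library raised the edgeR count to 1317 without replicate 1 and 5320 without replicate 2, fits in which the spread between WT libraries no longer entered. Leaving out either knockout library brought it to 0, with 1432 and 1501 genes at an unadjusted p under 0.05.

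**Figure D1:**
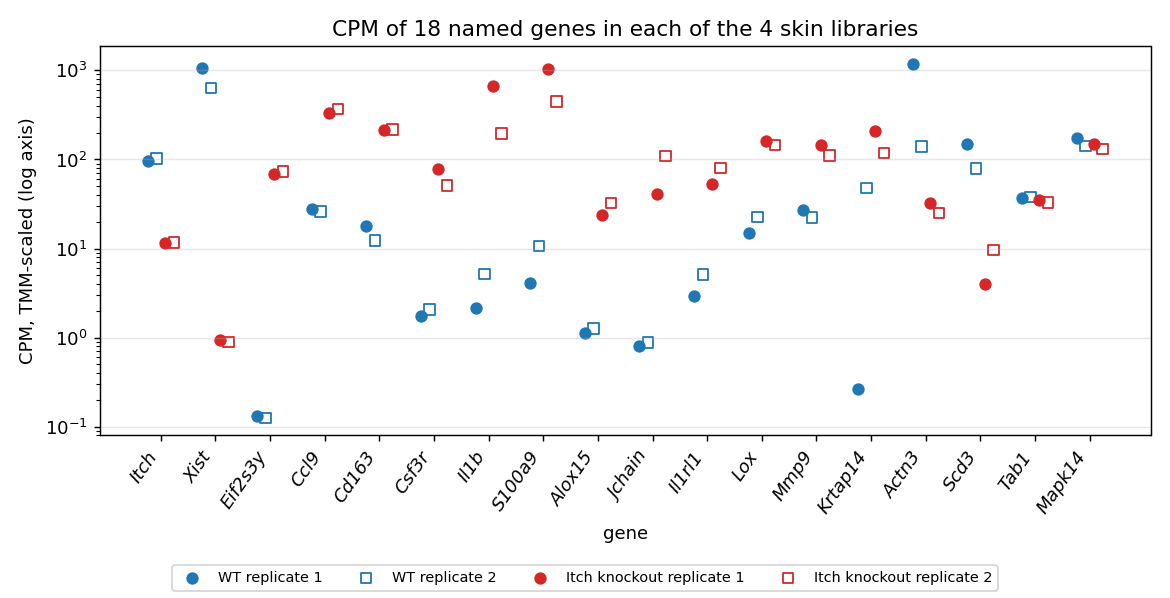
CPM (log axis) of 18 genes in each of the 4 libraries, with blue symbols for WT, red for the Itch knockout, filled circles for replicate 1 and open squares for replicate 2. Itch lies at 96.7 and 103 CPM in WT and at 11.7 CPM in both knockouts, Cd163 at 17.9 and 12.4 CPM in WT and 214 and 216 CPM in the knockouts, and Krtap14 and Actn3 differ between the WT libraries.

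Most genes of infiltrating and resident myeloid cells were higher in both knockout libraries. The macrophage and monocyte list rose with a median log2 fold change of 3.33 over 22 tested genes (camera adjusted p = 1.04e-23). That call was lost at adjusted p = 0.337 with an estimated correlation, a setting in which 4 libraries could hardly let any list pass. Cd163, a haemoglobin scavenger receptor of tissue macrophages, stood at 17.9 and 12.4 CPM in WT and 214 and 216 in the knockouts (log2 fold change 3.83, SE 0.25, adjusted p = 0.0548). Fcgr3, an Fc receptor, stood at 14.9 and 15.5 against 198 and 139 CPM. Over all genes 0 members passed in edgeR, while 20 passed adjusted over the list alone, 20 at an unadjusted p under 0.05 and 20 in DESeq2, all higher. The neutrophil list rose as well, with a median of 6.09 over 14 genes, or 5.57 with 2 genes of a group at 0 set at their bounds (adjusted p = 5.18e-14, and adjusted p = 0.337 with an estimated correlation). Csf3r, the receptor for the neutrophil growth factor G-CSF, stood at 1.73 and 2.08 CPM in WT and 79.1 and 51.0 in the knockouts. Of the 14, 0 passed over all genes, 11 adjusted over the list alone, 11 at an unadjusted p under 0.05 and 12 in DESeq2. Haemoglobin and other red blood cell genes were higher as well, a median of 3.23 over 6 genes (adjusted p = 1.66e-06, and adjusted p = 0.349 with an estimated correlation). Of these 6, 0 passed over all genes, 5 adjusted over the list alone and 5 each at an unadjusted p under 0.05 and in DESeq2. Hbb-bs, a beta globin, stood at 30.1 and 21.2 CPM in WT and 142 and 248 in the knockouts, and Hbb-bt at 4.47 and 3.03 against 40.4 and 87.5 CPM.

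Chemokines and innate cytokines showed the same direction. The chemokine list rose with a median of 3.83 over 20 genes (adjusted p = 1.24e-14, and adjusted p = 0.305 with an estimated correlation). Ccl9, a monocyte attractant, stood at 27.5 and 26.1 CPM in WT and 329 and 370 in the knockouts (log2 fold change 3.71, SE 0.17, adjusted p = 0.0509). Ccl6 stood at 48.0 and 29.0 against 543 and 503 CPM, and Ccl7 at 3.87 and 4.67 against 58.3 and 100.7 CPM. No member passed over all genes in edgeR, and 17 passed adjusted over the list alone, at an unadjusted p under 0.05 and in DESeq2, 16 higher and 1 lower each time. The innate cytokine list rose with a median of 4.09 over 15 genes, or 4.06 with 1 gene at its bound (adjusted p = 1.16e-08, and adjusted p = 0.305 with an estimated correlation). Osm, encoding oncostatin M, stood at 0.467 and 0.442 CPM in WT and 74.5 and 31.7 in the knockouts. Il24 stood at 0.133 and 0.379 against 16.2 and 34.02 CPM. Il19, of the same cytokine family, stood at 0.0667 and 0.316 against 10.9 and 27.8 CPM. Of the 15, 0 passed over all genes, 8 adjusted over the list alone, 9 at an unadjusted p under 0.05 and 9 in DESeq2, all higher.

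Cytokines fixed for naming in advance varied between the knockout libraries. Il1b stood at 2.13 and 5.18 CPM in WT and 664 and 196 in the knockouts (log2 fold change 6.87, SE 0.94, adjusted p = 0.0750). Tnf stood at 1.87 and 2.84 CPM in WT and 72.2 and 6.75 in the knockouts (adjusted p = 0.183), and Il6 at 0.200 and 0.442 against 4.29 and 23.4 CPM (adjusted p = 0.114). DESeq2 called all 3, with adjusted p = 8.57e-21 for Il1b, 0.000832 for Tnf and 5.79e-06 for Il6. Il11 was low in every library, 0.267 and 0.631 CPM against 0.695 and 1.59, and was not called by either tool (adjusted p = 0.326 in edgeR). Il17a had 3 counts in knockout replicate 1 and 0 in the other libraries, so a difference was not detectable at this depth.

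Most keratinocyte alarm and wound genes were higher in the knockouts. The antimicrobial alarm list rose with a median of 4.19 over 16 genes (adjusted p = 9.87e-12, and adjusted p = 0.337 with an estimated correlation). S100a9, a subunit of calprotectin made by neutrophils and stressed keratinocytes and also on the neutrophil list, stood at 4.13 and 10.7 CPM in WT and 1049 and 447 in the knockouts. The acute-phase gene Saa1 stood at 0.333 and 0.568 against 22.0 and 15.4 CPM, and Serpinb3a at 0.933 and 0.694 against 25.1 and 12.7 CPM. Of the 16, 0 passed over all genes, 11 adjusted over the list alone, 11 at an unadjusted p under 0.05 and 11 in DESeq2, all higher. The stress and wound keratin list rose with a median of 2.71 over 23 genes (adjusted p = 1.14e-09, and adjusted p = 0.442 with an estimated correlation). Without WT replicate 1 the list had a median of 1.95, and without WT replicate 2 it had a median of 5.51. Small proline-rich proteins of the cornified envelope led it: Sprr2d stood at 0.800 and 4.80 CPM in WT and 154 and 99.7 in the knockouts, and Sprr2f at 0.200 and 0.568 against 11.9 and 22.9 CPM. Of the 23, 0 passed over all genes, 9 adjusted over the list alone and 13 in DESeq2, all higher, and 14 higher and 1 lower had an unadjusted p under 0.05.

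Barrier and basal keratinocyte genes went both ways and neither list passed. The cornified envelope list had 10 of 39 genes with both knockouts above both WT libraries and 16 with both below (median -0.22, mean 0.23, adjusted p = 0.137). Flg2, a filaggrin-like barrier protein, stood at 884 and 527 CPM in WT and 167 and 99.7 in the knockouts, and Abca12, a lipid transporter of lamellar granules, at 328 and 234 against 110 and 93.7 CPM. The transglutaminase gene Tgm5 stood at 116 and 100.9 against 57.5 and 55.1 CPM. No member passed over all genes, 1 higher and 6 lower passed adjusted over the list alone, 2 higher and 13 lower had an unadjusted p under 0.05, and DESeq2 called 3 higher and 11 lower. The direction of this list rested on the WT libraries: it passed as lower without WT replicate 1 (adjusted p = 0.00220) and as higher without WT replicate 2 (adjusted p = 0.00920). The basal keratinocyte list had a median of -0.14 over 12 genes (adjusted p = 0.545), which was 0.05 without WT replicate 1, -0.45 without WT replicate 2, -0.31 without knockout replicate 1 and -0.05 without knockout replicate 2. Krt15, a basal and hair bulge keratin, stood at 2250 and 1322 CPM in WT and 582 and 625 in the knockouts, while Krt14 stood at 1617 and 1888 against 2979 and 3475 CPM. Of the 12, 0 passed over all genes, 2 higher and 1 lower adjusted over the list alone, 3 higher and 3 lower at an unadjusted p under 0.05, and 2 higher and 3 lower in DESeq2.

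Most type 2, eosinophil and mast cell genes were higher in both knockout libraries. The type 2 list rose with a median of 1.86 over 21 genes (adjusted p = 1.33e-09, and adjusted p = 0.305 with an estimated correlation). Chil3, encoding a chitinase-like protein, stood at 0.467 and 0.505 against 80.0 and 36.3 CPM. The related Chil4 stood at 0 and 0.0631 against 10.6 and 19.7 CPM. Alox15, a lipoxygenase also on the eosinophil list, stood at 1.13 and 1.26 against 23.6 and 32.4 CPM (log2 fold change 4.54, SE 0.32, adjusted p = 0.0548). No member passed over all genes, 13 higher and 2 lower passed adjusted over the list alone and at an unadjusted p under 0.05, and DESeq2 called 10 higher and 2 lower. The eosinophil list rose with a median of 2.81 over 6 genes (adjusted p = 4.88e-07, and adjusted p = 0.327 with an estimated correlation). Ccr3, the eotaxin receptor, stood at 0.200 and 0.442 against 9.79 and 8.22 CPM. Of the 6, 0 passed over all genes, 5 adjusted over the list alone and at an unadjusted p under 0.05, and 4 in DESeq2. The mast cell list rose with a median of 2.19 over 12 genes (adjusted p = 4.58e-10, and adjusted p = 0.337 with an estimated correlation). Il1rl1, the receptor of interleukin-33, stood at 2.93 and 5.11 against 53.0 and 79.9 CPM, and Mcpt8, a protease of basophils, at 0.0667 and 0.189 against 7.58 and 12.9 CPM. Of the 12, 0 passed over all genes, 10 adjusted over the list alone and at an unadjusted p under 0.05, and 9 in DESeq2.

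Type 17 genes were sparsely measured and the list did not pass. Of 13 genes written down, 6 could be tested (median 0.24, adjusted p = 0.467), with 0 past over all genes, 1 adjusted over the list alone, 3 at an unadjusted p under 0.05 and 1 in DESeq2. Il17ra, the interleukin-17 receptor chain, stood at 34.2 and 38.1 CPM in WT and 64.6 and 80.1 in the knockouts. Il23a stood at 0.333 and 0.631 against 4.61 and 1.40 CPM, and Il1r1 at 63.1 and 52.6 against 81.2 and 117 CPM.

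The T cell, B cell and dendritic cell lists rose, and the gamma delta T cell list did not pass. The T cell list rose with a median of 1.15 over 23 genes (adjusted p = 7.12e-05, and adjusted p = 0.337 with an estimated correlation), and the median was 0.65 without knockout replicate 1. Trac, the constant segment of the T cell receptor alpha chain, stood at 1.00 and 1.07 CPM in WT and 5.24 and 4.33 in the knockouts. Thy1, which fibroblasts also make, stood at 127 and 156 against 305 and 323 CPM. Of the 23, 0 passed over all genes, 4 adjusted over the list alone, 9 at an unadjusted p under 0.05 and 8 in DESeq2, all higher. The B cell and plasma cell list rose with a median of 2.09 over 14 genes (adjusted p = 0.000143, and adjusted p = 0.384 with an estimated correlation). Its median was 0.76 without knockout replicate 2, and its call was lost without WT replicate 2 (adjusted p = 0.0952). Jchain, which joins secreted antibody units, stood at 0.800 and 0.884 against 40.9 and 109 CPM, and the kappa constant gene Igkc at 2.93 and 1.64 against 99.98 and 262 CPM. Of the 14, 0 passed over all genes, 6 adjusted over the list alone, 7 at an unadjusted p under 0.05 and 4 in DESeq2. The dendritic and Langerhans cell list rose with a median of 1.15 over 18 genes (adjusted p = 2.72e-06, and adjusted p = 0.396 with an estimated correlation). Ccr7, a receptor of migrating dendritic cells, stood at 0.267 and 0.758 against 9.85 and 7.07 CPM, and Batf3 at 1.47 and 1.01 against 7.39 and 6.37 CPM. Of the 18, 0 passed over all genes, 12 adjusted over the list alone, 13 at an unadjusted p under 0.05 and 12 in DESeq2. The gamma delta T cell list did not pass (11 genes, median -0.38, adjusted p = 0.436), with 0 past over all genes, 1 adjusted over the list alone, 2 higher and 1 lower at an unadjusted p under 0.05, and 1 in DESeq2. Its median was -0.50 without WT replicate 1, -0.72 without WT replicate 2, -1.10 without knockout replicate 1 and -0.27 without knockout replicate 2. Of the 11 members, 3 were fitted higher and 8 lower, and the 2 with the smallest p, Fgf7 and Klrg1, were among those higher. Fgf7 stood at 9.33 and 10.7 against 25.01 and 25.9 CPM, and Klrg1 at 0.0667 and 0.253 against 1.14 and 1.53 CPM. Which cells made Fgf7 and Klrg1 was not tested, so their rise need not come from gamma delta T cells. The members Tcrg-V5 and Trdv4, reported further below, were fitted lower but not called.

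Interferon-responsive genes were modestly higher. The type I interferon list rose with a median of 1.17 over 22 genes (adjusted p = 1.12e-05, and adjusted p = 0.536 with an estimated correlation), and the median was 0.61 without knockout replicate 1. Bst2, an antiviral tether, stood at 26.6 and 22.1 CPM in WT and 81.5 and 53.6 in the knockouts, and Zbp1 at 7.27 and 5.37 against 35.2 and 18.5 CPM. Of the 22, 0 passed over all genes, 7 adjusted over the list alone, 12 at an unadjusted p under 0.05 and 8 in DESeq2, all higher. The interferon gamma list rose with a median of 0.98 over 18 genes (adjusted p = 0.00106, and adjusted p = 0.626 with an estimated correlation). Its call was lost without knockout replicate 1 (median 0.20, adjusted p = 0.241) and without WT replicate 2 (median 0.75, adjusted p = 0.265), and its median was 1.496 without WT replicate 1. Socs1, a feedback inhibitor of cytokine signalling, stood at 6.60 and 6.25 against 16.7 and 20.1 CPM, and Nos2 at 1.27 and 0.316 against 24.6 and 2.99 CPM. Of the 18, 0 passed over all genes, 0 adjusted over the list alone, 4 at an unadjusted p under 0.05 and 2 in DESeq2.

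Matrix genes and most of the proteases that remodel matrix were higher in both knockout libraries. The dermal matrix and fibroblast list rose with a median of 1.99 over 24 genes (adjusted p = 5.50e-20, and adjusted p = 0.337 with an estimated correlation), and all 24 had both knockouts above both WT libraries. Lox, which crosslinks collagen and elastin, stood at 15.1 and 22.5 CPM in WT and 159 and 146 in the knockouts. Eln, encoding elastin, stood at 14.6 and 15.1 against 117 and 81.3 CPM, and the collagen gene Col5a1 at 52.1 and 74.8 against 487 and 380 CPM. Of the 24, 0 passed over all genes, 23 adjusted over the list alone, 23 at an unadjusted p under 0.05 and 21 in DESeq2. The metalloproteinase list rose with a median of 2.36 over 15 genes (adjusted p = 8.29e-12, and adjusted p = 0.337 with an estimated correlation). Mmp9, a gelatinase also made by neutrophils, stood at 27.1 and 22.3 against 144 and 111 CPM, Mmp19 at 13.1 and 11.4 against 59.1 and 44.5 CPM, and the neutrophil collagenase gene Mmp8 at 0.200 and 0.316 against 28.5 and 8.98 CPM. Of the 15, 0 passed over all genes, 12 adjusted over the list alone, 13 at an unadjusted p under 0.05 and 9 in DESeq2. The endothelial list rose with a median of 0.83 over 18 genes (adjusted p = 2.08e-05, and adjusted p = 0.509 with an estimated correlation), 1.35 without WT replicate 1 and 0.44 without WT replicate 2. The adhesion molecule gene Vcam1 stood at 5.07 and 5.68 against 42.9 and 30.5 CPM, and Pdpn at 12.9 and 23.5 against 89.6 and 105 CPM. Of the 18, 0 passed over all genes, 5 adjusted over the list alone, 8 at an unadjusted p under 0.05 and 6 in DESeq2.

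Hair, muscle, fat and gland genes depended on which WT library entered. The skeletal muscle list fell with a median of -3.32 over 21 genes (adjusted p = 1.65e-08, and adjusted p = 0.530 with an estimated correlation), and the median was -1.19 without WT replicate 1. Pvalb, a calcium buffer of fast fibres, stood at 1147 and 277 CPM in WT and 43.8 and 48.8 in the knockouts. Of the 21, 0 passed over all genes, 17 adjusted over the list alone, 17 at an unadjusted p under 0.05 and 15 in DESeq2, all lower. The hair keratin list rose with a median of 1.41 over 37 genes (adjusted p = 1.76e-05, and adjusted p = 0.642 with an estimated correlation), 0.43 without WT replicate 1 and 7.61 without WT replicate 2. Krt84 stood at 1.53 and 14.9 against 18.2 and 25.6 CPM. Of the 37, 0 passed over all genes, 0 adjusted over the list alone, 1 at an unadjusted p under 0.05 and 1 in DESeq2. The adipocyte list fell with a median of -0.51 over 20 genes (adjusted p = 0.0388, and adjusted p = 0.743 with an estimated correlation). Its median was 0.05 without WT replicate 1 and -0.996 without WT replicate 2, and its call was lost without knockout replicate 1 (adjusted p = 0.0659). Lep, encoding leptin, stood at 165 and 68.8 against 16.3 and 42.6 CPM. Of the 20, 0 passed over all genes, 0 adjusted over the list alone, 2 lower at an unadjusted p under 0.05 and 1 in DESeq2. The sebaceous list fell with a median of -0.26 over 22 genes (adjusted p = 0.0467, and adjusted p = 0.556 with an estimated correlation). Its median was 0.02 without WT replicate 2 (adjusted p = 0.450) and -0.42 without WT replicate 1, and its call was lost without knockout replicate 1 (adjusted p = 0.0815). Scd3, a sebaceous fatty acid desaturase, stood at 149 and 79.5 against 4.04 and 9.62 CPM (log2 fold change -4.06, SE 0.60). Awat2, a wax synthase, stood at 47.2 and 72.5 against 7.45 and 20.9 CPM. Of the 22, 0 passed over all genes, 1 adjusted over the list alone, 3 lower at an unadjusted p under 0.05 and 3 in DESeq2.

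Pigment, nerve and dividing-cell genes moved with the WT libraries too. The melanocyte list did not pass (13 genes, median -0.09, mean 0.16, adjusted p = 0.350), yet passed as lower without WT replicate 1 (adjusted p = 0.0290) and as higher without WT replicate 2 (adjusted p = 0.000226). Its members gave 0 past over all genes and over the list alone, 1 at an unadjusted p under 0.05 and 0 in DESeq2. Asip, the agouti signal, stood at 0.667 and 0.505 against 1.58 and 2.23 CPM (adjusted p = 0.153), and Gpnmb at 33.5 and 160 against 174 and 142 CPM. The Schwann cell and nerve list did not pass (12 genes, median -0.65, adjusted p = 0.0920), with a median of -0.22 without WT replicate 1, yet passed as lower without WT replicate 2 (median -1.05, adjusted p = 0.00483) and without knockout replicate 2 (adjusted p = 0.0299). Mbp, a myelin protein, stood at 210 and 71.0 against 52.9 and 48.4 CPM, and 0 members passed over all genes or over the list alone, 1 at an unadjusted p under 0.05 and 2 in DESeq2. The cell cycle list rose with a median of 0.46 over 30 genes (adjusted p = 0.0266, and adjusted p = 0.776 with an estimated correlation). Its median was 0.03 without WT replicate 1 (adjusted p = 0.479) and 1.05 without WT replicate 2, and its call was lost without knockout replicate 2 (adjusted p = 0.0880). Mcm3, of the replication helicase, stood at 19.9 and 46.8 against 70.1 and 76.7 CPM, while the mitotic gene Cenpf stood at 39.7 and 50.8 against 31.4 and 31.1 CPM. Of the 30, 0 passed over all genes or over the list alone, 1 lower at an unadjusted p under 0.05 and 0 in DESeq2.

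Transcripts of the p38 kinase cascade and of Itch partners showed no shared direction. The p38 list had a median of -0.16, a mean of 0.02 and adjusted p = 0.626 over 25 genes. Tab1, an activator of p38 described as an Itch substrate, stood at 36.5 and 37.7 CPM in WT and 35.5 and 32.8 in the knockouts (log2 fold change -0.12, SE 0.17), and Mapk14, encoding p38 alpha, at 176 and 142 against 150 and 132 CPM (log2 fold change -0.18, SE 0.18). The list members with both knockouts above both WT libraries included Zfp36, an mRNA-decay protein gene that is also on the immediate early and heat shock list. It stood at 76.6 and 81.8 against 219 and 194 CPM, and the phosphatase gene Dusp1 at 68.8 and 35.5 against 276 and 164 CPM. Of the 25, 0 passed over all genes, 1 adjusted over the list alone, 4 higher and 4 lower at an unadjusted p under 0.05, and 3 higher in DESeq2. The list of described partners had a median of -0.12, a mean of 0.07 and adjusted p = 0.626 over 25 genes. Junb, also on the immediate early and heat shock list, stood at 127 and 175 against 514 and 428 CPM (log2 fold change 1.64, SE 0.24, adjusted p = 0.0755). Notch1 stood at 158 and 146 against 71.9 and 71.4 CPM (log2 fold change -1.08, SE 0.14, adjusted p = 0.0703) and Egr3 at 52.2 and 62.0 against 26.0 and 31.7 CPM. Of the 25, 0 passed over all genes, 1 higher and 1 lower adjusted over the list alone, 4 higher and 3 lower at an unadjusted p under 0.05, and 4 higher and 2 lower in DESeq2. The Nedd4 family list fell with a median of -0.46 over 8 genes (adjusted p = 0.0110, and adjusted p = 0.426 with an estimated correlation). Itch is on it, and without Itch the call was lost (median -0.44, adjusted p = 0.143). The median was -0.13 without WT replicate 1, -0.70 without WT replicate 2 and -0.28 without knockout replicate 2. Smurf2 stood at 107 and 84.2 against 62.3 and 64.6 CPM, and Nedd4 at 723 and 522 against 474 and 445 CPM. Of the 8, 0 passed over all genes, 1 adjusted over the list alone, 2 lower at an unadjusted p under 0.05 and 1 in DESeq2.

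Lists kept as signs of tissue handling and time of day gave mixed results. The immediate early and heat shock list rose with a median of 0.97 over 20 genes (adjusted p = 1.39e-06, and adjusted p = 0.305 with an estimated correlation). Fos stood at 10.9 and 13.8 CPM in WT and 121 and 118 in the knockouts (log2 fold change 3.28, SE 0.20, adjusted p = 0.0529). Of the 20, 0 passed over all genes, 12 adjusted over the list alone, 12 higher and 1 lower at an unadjusted p under 0.05, and 11 in DESeq2. The mitochondrially encoded list fell with a median of -0.97 over 9 genes (adjusted p = 0.000762, and adjusted p = 0.533 with an estimated correlation), and the median was -0.60 without WT replicate 1. Reads of mitochondrial genes made up 2.29% and 1.41% of gene reads in WT and 1.06% and 0.756% in the knockouts. The skeletal muscle list ranked the libraries the same way, with sums of 26010 and 3939 CPM in WT and 1890 and 1645 in the knockouts. Whether the mitochondrial fall followed muscle content or tissue handling was not tested. mt-Cytb stood at 4706 and 2912 against 2158 and 1700 CPM, and mt-Nd5 at 3658 and 1495 against 918 and 426 CPM. Of the 9, 0 passed over all genes, 0 adjusted over the list alone, 5 lower at an unadjusted p under 0.05 and 4 in DESeq2. The circadian list did not pass (17 genes, median 0.08, adjusted p = 0.626). Its median was 0.46 without WT replicate 1, -0.03 without WT replicate 2, -0.11 without knockout replicate 1 and 0.13 without knockout replicate 2. Per1 stood at 37.0 and 27.4 against 118 and 104 CPM, and Bhlhe40 at 70.5 and 78.5 against 164 and 183 CPM. Of the 17, 0 passed over all genes, 4 higher and 2 lower adjusted over the list alone, 5 higher and 3 lower at an unadjusted p under 0.05, and 4 higher and 2 lower in DESeq2.

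**Figure D2:**
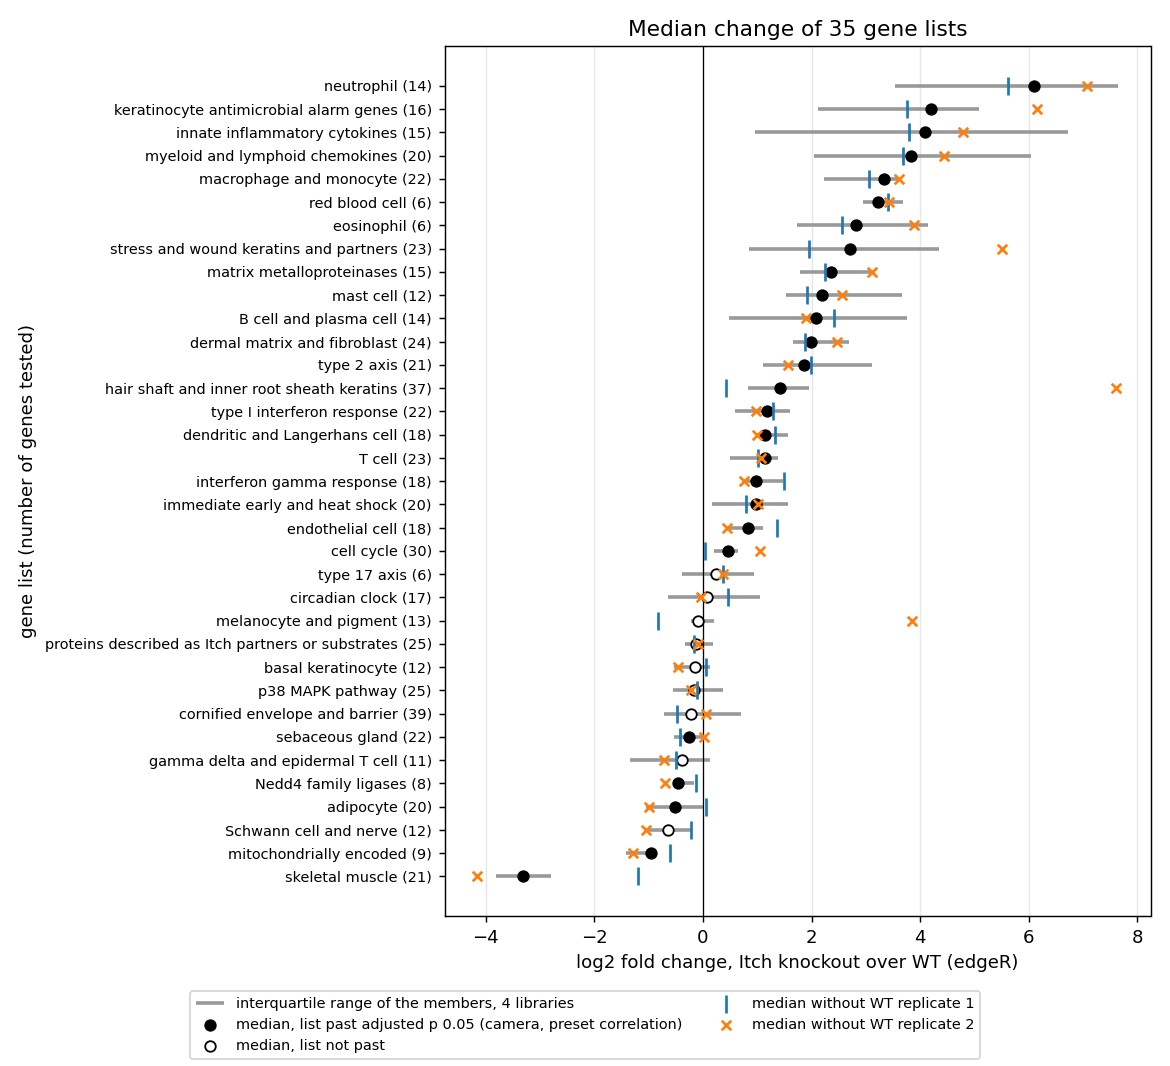
Median log2 fold change of each gene list except the sex-linked list, knockout over WT on the horizontal axis, with the number of genes tested beside each name, grey bars for the interquartile range over members, filled circles for lists past the list test and open circles for the others. The hair keratin median moves from 1.41 with all libraries to 0.43 without WT replicate 1 (blue) and 7.61 without WT replicate 2 (orange), while the macrophage median stays between 3.06 and 3.60 under those choices.

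Genes near Itch were compared with the rest of the genome. Within 5 Mb of Itch, 0 of 138 other tested genes passed in edgeR, against 1 of 16512 elsewhere (two-sided Fisher's exact p = 1). With 1 gene called in all, this comparison decides nothing. Of the 138, 30 had an unadjusted p under 0.05, beside 3802 of all 16651 tested genes. With DESeq2 calls, a comparison added after seeing the data, 14 of 138 nearby genes passed against 2314 of 16512 elsewhere (10.1% against 14.0%, two-sided Fisher's exact p = 0.218, odds ratio 0.693, 95% interval 0.367 to 1.21).

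Of 112 genes chosen for naming, 21 share exon sequence with a gene of the opposite strand, among them Il1b, Junb, Notch1, Zfp36, Dusp1, Lox, Eln, Col5a1, Mmp19, Vcam1, Bhlhe40, mt-Nd5 and Xist, and their counts are uncertain because strand use in counting is not given in the sources used here. Counts of near-identical copies, such as Sprr2, Krtap, Chil, globin and immunoglobulin genes, are uncertain as well.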

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

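The fits without X and Y genes and without robust moderation, the adjusted p under 0.10, the DESeq2 calls near Itch and the Nedd4 family list without Itch were tests chosen only after the results were seen. The count of 1 changed gene was the same with DESeq2 size factors, TMM without the top 200 genes, library size alone, the stricter filter, the test against a fold of 1.5 and no robust moderation. It was 488 without a filter, 2329 with DESeq2, 69 with the newer quasi-likelihood test, 789 at an adjusted p under 0.10, 0 with limma-voom (3566 at an unadjusted p under 0.05) and 0 without X and Y genes (3649), where Eif2s3y is left out by construction. It ranged from 0 to 5320 over the libraries left out, where by construction the spread came from the intact pair alone. Itch passed without a filter (log2 fold change -3.07), with DESeq2 (-3.10) and with the newer quasi-likelihood test (-3.09), and lay between -3.14 and -3.04 over the libraries left out. With the replicate number as a block the count was 0 (3998 at an unadjusted p under 0.05) and 25 lists passed. Nothing in the labels pairs the numbers, and deviations of same-numbered libraries correlated at 0.186 across genes. Of 36 lists, 27 passed, between 24 and 27 over the libraries left out, 0 with an estimated correlation and 5 with fry. With 4 libraries, the estimated correlation could hardly let any list pass. Lists turned direction in these cases, and the cause was not tested: gamma delta T cell with the stricter filter (adjusted p = 0.647) and p38 with fry (adjusted p = 0.946). Over the libraries left out, some lists also turned, with camera adjusted p from 2.93e-05 to 0.302 (adipocyte), 7.87e-07 to 0.479 (cell cycle), 0.189 to 0.827 (circadian), 0.00220 to 0.386 (cornified envelope), 0.000226 to 0.970 (melanocyte), 0.566 to 0.982 (p38) and 3.33e-06 to 0.450 (sebaceous). Gpnmb lay between -0.024 and 2.24 (log2 fold change). The sebaceous call was also lost with TMM without the top 200 genes, library size alone, no filter, the stricter filter, limma-voom, the block and without X and Y genes, and the adipocyte call with no filter, the stricter filter and the block. Near Itch no window of 1, 5 or 10 Mb passed, either with DESeq2 calls or with edgeR, whose 1 call in all decides nothing. Depth limited genes such as Il17a, with 3 counts in 1 library.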

Other observations

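Tests chosen only after the result was seen were those on WT replicate 1, blood and sex for the immune genes, all 3 on the hair keratins, and the DESeq2 reading near Itch. The Skint genes, Tcrg-V5, Trdv4, Fcgr2b, Clec10a, Folr2, Pf4 and 2310005A03Rik were chosen after their values were seen. The Skint genes, which encode butyrophilin-like proteins of keratinocytes and thymus epithelium, were lower in both knockout libraries for 11 of 11 annotated members, against 30.0% of all tested genes. Their median log2 fold change was -1.73, from -3.10 to -0.59. In edgeR 0 of the 11 passed, 10 had an unadjusted p under 0.05, and DESeq2 called 10. Skint5 stood at 104 and 38.6 CPM in WT and 9.35 and 7.33 in the knockouts, and Skint9 at 131.5 and 96.9 against 31.7 and 34.9 CPM. Tcrg-V5 and Trdv4, receptor segments used by epidermal T cells, stood at 4.80 and 1.52 against 0.632 and 0.701 CPM and at 7.20 and 2.02 against 1.45 and 0.765 CPM. Neither was called, with adjusted p = 0.182 and 0.229 in edgeR and 0.103 and 0.138 in DESeq2. Their log2 fold changes of -2.23 and -2.05 were -1.18 and -0.86 without WT replicate 1. Both had adjusted p under 0.05 without WT replicate 2, where the spread came from the knockout libraries alone, so this is no evidence of a fall.

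Among genes outside the lists, 4 with small p were picked after their values were seen, and which cells made them was not tested. Fcgr2b, an inhibitory Fc receptor, stood at 13.6 and 16.7 CPM in WT and 212 and 211 in the knockouts, and Clec10a, a lectin of macrophages and dendritic cells, at 14.9 and 13.2 against 201 and 167 CPM. Folr2 stood at 12.7 and 9.78 against 74.6 and 75.4 CPM, and Pf4 at 9.40 and 9.72 against 69.2 and 83.0 CPM. All 4 had an edgeR adjusted p between 0.0509 and 0.0548. 2310005A03Rik, a lincRNA gene on the minus strand of GRCm38 chromosome 2 from 155097789 to 155100081, next to the 5′ end of Itch, stood at 12.7 and 17.1 CPM in WT and had 0 counts in both knockouts. It was at least 157-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 0.0554). The Itch allele is not named in the sources used here, so whether it spans this gene is not known.

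Immune genes were higher in the knockouts. The make-up of WT replicate 1 as the whole cause is argued against by the macrophage, neutrophil and chemokine medians, which kept at least 0.918 of their size without that library. Blood in the tissue stays open. It needs the red blood cell list to be higher, and that list had a median log2 fold change of 3.23 (interquartile range 2.94 to 3.68). Against blood, knockout replicate 1 over replicate 2 had medians of 1.21 for the neutrophil list, 0.43 for the macrophage list and -1.20 for the red blood cell list. That is a comparison of single libraries and does not decide. Summed over members, the red blood cell list stood at 263 and 540 CPM in knockout replicates 1 and 2. The neutrophil list summed to 2828 and 1187 CPM there, and the macrophage list to 5357 and 3781 CPM. How much immune RNA that amount of blood would carry was not tested. The sex of the animals cannot be told apart from the genotype, since 0 groups held libraries of both sexes. An effect of the Itch genotype, of lesions, of blood or of sex may each contribute.

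Hair keratins were lower in WT replicate 1 than in WT replicate 2 for 37 of 37 genes, with a median of -5.74 on the log2 scale. Fewer follicles in the piece of skin as the whole cause is argued against by 14 genes of the permanent follicle, whose median was -0.68 (interquartile range -0.97 to -0.53). Knockout RNA in WT replicate 2 is argued against by the Y-linked genes, at 0.191% of the knockout level there, against 92.2% for the hair keratins. A different phase of the hair cycle may account for the pattern, since the permanent follicle median of -0.68 lay within 1 log2 unit of 0, as that explanation needs. It remains a hypothesis, because the hair keratin values were known when it was framed. WT replicate 1 over replicate 2 also had median log2 ratios of 2.90 for the skeletal muscle list and 1.20 for the adipocyte list. The WT libraries thus differed in more than hair, and whether that bears on the hair keratins was not tested.

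By Xist and the Y-linked genes, 2 libraries were female and the other two male. The share of genes near Itch was not decided by edgeR calls, where the upper 95% bound of the odds ratio was 4666, and with DESeq2 calls that bound was 1.21. For time of day, 0 of 6 clock genes passed in edgeR, which called 1 gene in all and so decides nothing. DESeq2 called 2, where the explanation was set to need all 6 and fewer than 4 to count against it. They were Arntl (log2 fold change -1.47, SE 0.23) and Npas2 (-2.78, SE 0.57). The other side of the clock was to move the opposite way. Its log2 fold changes were -1.07 (SE 0.50) for Nr1d1, 0.08 (SE 0.37) for Nr1d2, 0.20 (SE 0.28) for Per3 and 0.53 (SE 0.49) for Dbp. Nr1d1 and Dbp also differed between WT replicates 1 and 2, at 172 and 65.2 CPM and at 25.3 and 10.2 CPM. On the whole circadian list of 17 genes DESeq2 called 4 higher and 2 lower. Per1 and Bhlhe40, not among the 6, were higher. Read with DESeq2 calls, the rule set in advance counts against a different harvest time, and Nr1d1 was fitted the same way as Arntl and Npas2. The question is still left open here, because edgeR decided nothing and Per1 and Bhlhe40 were higher.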
